A study of Homo sapiens with 78 samples.

How the data were processed

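The study measured miRNAs on single-colour Agilent human miRNA arrays in culture medium and in cells of A549, HepG2, U87, T98 and BEAS, with serum or after a change to serum-free medium. Per the labels' protocols, total RNA was isolated from fixed amounts of medium or cells, and a fixed mass of RNA was labelled with cyanine 3 by ligation. A fixed mass hides a difference in the amount of RNA between medium and cells, so each value is a share of the labelled RNA. Per the submitters' processing notes, the images were read with Agilent Feature Extraction 9.1. The deposited array files give 1 linear intensity per spot, per the file headers with a mean and SD of the green background; whether background was subtracted is not given in the sources used here. The files hold 1 constant flag per spot, so outlier and detection flags of the scanner and the slide of each array were not used here. The deposited series table holds 1 log2 value per probe and array, with column medians between 5.24 and 5.25. Its columns share nearly the same quantiles, as quantile normalization between arrays would give, but per the labels the method the authors used for this log2 table is not stated.

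Each array had 15744 spots for 2421 miRNA probes, 2125 human and 296 viral. The human probes made up 722 features, of which 9 name several miRNAs. The median of a probe's replicate spots was taken. The background of an array was the median over its viral miRNA spots, and a spot counted as above background when it exceeded this by 3 robust SDs. A probe was detected when at least 50% of its spots were, and a miRNA when at least 1 of its probes was. The background was subtracted and probes of a miRNA were averaged on the linear scale. Arrays of a comparison were scaled by the 75th percentile over the miRNAs detected on all its arrays, or, where fewer than 20 were, on at least 50% of them, and the divisor was not allowed below the array's detection threshold (a guard for dim arrays). A floor common to the comparison was applied before taking log2. It was the median over its arrays of the scaled lowest signal of a detected probe. A miRNA can thus be detected and still lie at the floor. Human miRNAs detected on at least as many arrays as the smaller arm holds were tested. The depth of an array is its signal over background. Detection needs 3 SDs over the background, which ran from 1.62 to 320.6 intensity units, and between 0 and 5 spots per array were saturated. A miRNA seen in only 1 arm, or at the floor on all arrays of the other, is given as a bound against the detection threshold of the other.

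Comparisons, groups, fixed lists and the rule for naming miRNAs were written before the data were examined. limma 3.58.1 in R 4.3.3 fitted each comparison (lmFit and eBayes, time or cell line as a factor), with Benjamini-Hochberg adjusted p at a threshold of 0.05. Compared were medium and cells in A549 and HepG2 with and without serum, serum-free and serum arrays within each compartment, medium of 4 lines at 2 h, slopes on log2 of hours plus 1 in serum-free medium, the interactions with cell line, and pellets against concentrated supernatants. The 12 miRNAs highest and the 12 lowest past the threshold, in the same direction at every time, are named in full (the 10 at each end where there is 1 array per condition). Fixed lists of miRNA families, clusters and tissue-associated miRNAs were tested with fry (in 1 direction, and mixed) and with camera (preset correlation 0.01, and estimated) where at least 3 members were tested. The list of G-rich minor and recently annotated miRNAs has 67 members, 50 of them on the array, and shares miR-134 and miR-494 with the chromosome 14 cluster. Numbers of detected miRNAs were compared by two-sided exact permutation. Comparisons with 1 array per condition were given as values, with list medians placed among 10000 random lists of the same size matched on mean level. Other splits of the arrays, at most 100 per comparison, were fitted in the same way. The fits were tested on simulated data. With 200 simulated miRNAs, 40 of them changed 4-fold, between 57 and 86.4% of the changed ones were recovered in the 4 comparisons of medium with cells, and 74.5% for the interaction. Of those changed 2-fold, between 0.375% (HepG2 with serum, where 40% of the calls were false) and 48.1% were recovered in these 4, and 24.9% for the interaction, so most simulated changes of that size were missed. The simulated values had no floor, detection filter or scaling, so these rates may not hold for the arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files, ran the permutation tests and drew the plots.

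Alternatives tried were scaling over all human miRNAs, no scaling, quantile normalization, normexp with an offset of 50, the brightest probe, no filter, detection on all arrays of an arm, the deposited log2 table of the authors, a mean-variance trend, no time factor, added control arrays, untransformed hours, omitting U87 pairs, detection by a single spot, and each array left out. Added after seeing the data were no guard, no background subtraction, means over spots, negative-control spots for detection, omitting dim arrays, A549 second samples alone, and the raised baseline as a block or as a split at a ratio of 0.15 between an array's lowest spots and its background. The replicate numbers of A549 were not used to pair medium with cells in the main fit. Deviations from the mean of each time correlated at 0.13, 0.14 and 0.071 between medium and cells at 2, 6 and 24 h. Such low correlations over miRNAs do not exclude a pairing or a batch. On medium arrays miR-638 was higher in replicate 1 than in replicate 2 at each time, at 7.46 against 5.26 at 24 h. On cell arrays it was lower in replicate 1 at each time. No 2 replicates shared identical probe values (0 of 2125). Controls were left out of the fits of medium, cells and serum, since the labels give them no time, as was the A549 medium array at 2 h whose serum status is not stated. The T98 pellet, whose serum status is not stated either, was kept in the fit of pellets.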

Results

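Agilent human microRNA (miRNA) arrays measured small RNA in total RNA from culture medium or from cells of 5 human lines on 78 arrays, 52 of medium and 26 of cells. A549 (lung adenocarcinoma) had 19 medium and 11 cell arrays, HepG2 (liver carcinoma) 16 and 9, U87 (glioma) 10 and 2, T98 (glioma) 5 and 3, and BEAS (bronchial epithelium) 2 and 1. Whole medium or whole cells, taken at stated times with serum or after a change to serum-free medium, made up 48 arrays, 1 of them with no serum status stated. The others held concentrated medium, supernatants, pellets, nuclear or cytoplasmic RNA, an RNase-treated medium or controls. Each array carried 722 human and 76 viral miRNA features. The median background was 14 intensity units, from 1.62 to 320.6 per array. The number of human features detected ran from 8 to 319 on medium arrays, with a median of 57.5, and from 9 to 135 on cell arrays, with a median of 59. The number of arrays limits the precision of every comparison, and the labels do not say whether replicates are separate cultures. On 23 arrays the lowest spots lay at 0.191 or more of the array's background, against at most 0.0867 on the others. These arrays, with a raised baseline, are treated below as a batch found in the values. Differences are on the log2 scale, relative to the miRNAs detected in each comparison, with standard errors.

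The first question was which miRNAs serum-deprived cells leave in their medium relative to their own content. In A549, miR-638 was 5.28 ± 0.95 higher in medium than in cells (6 arrays each, adjusted p = 0.00437) and miR-1225-5p was 3.46 ± 0.67 higher (adjusted p = 0.00506). miR-671-5p was detected on 6 of 6 medium arrays and on 0 of 6 cell arrays, at least 6.91-fold higher (adjusted p = 1.5e-05). miR-923, an annotation since withdrawn as a ribosomal RNA fragment, was 3.25 ± 0.71 higher, and miR-494 was 2.26 ± 0.72 higher. Members of widely expressed families were lower in medium. miR-29b differed by −2.33 ± 0.36, miR-27b by −1.91 ± 0.48, miR-29a by −1.90 ± 0.62, miR-23a by −1.88 ± 0.51, miR-23b by −1.70 ± 0.34, miR-19b by −1.62 ± 0.30 and miR-30a by −1.18 ± 0.39. On the 6 medium arrays miR-23b was detected on 1, miR-29b on 2, miR-27b, miR-29a, miR-19b and miR-30a on 3 and miR-23a on 4. The size of these decreases is therefore partly set by the floor. The guard set the divisor of 3 arrays, the dim medium arrays of replicate 1 at 2, 6 and 24 h. As scaled for the slopes on time, miR-29a, miR-27b and miR-30a lay at the floor on these and above it on those of replicate 2. On replicate 2, miR-19b also lay at the floor at 24 h and miR-23a at 2 h. These decreases thus partly follow a dim series of arrays. The smaller decreases of miR-106b, −0.57 ± 0.19, and of miR-19a, given without a size because it lay at the floor on all medium arrays, turned to 0.17 and 0.28 under the normexp background correction. In limma, 14 of 43 tested miRNAs differed between medium and cells, 5 higher and 9 lower, each in the same direction at 2, 6 and 24 h.

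Fixed lists of miRNAs were tested in A549 as well. Of 8 tested members of the list of G-rich minor and recently annotated miRNAs, 5 were higher and 0 lower in medium, or 6 and 0 adjusted over the list alone. The list moved up on balance (fry adjusted p = 0.00153), which tests the list's own members and does not compare them with other miRNAs. Among the other lists, 3 of 4 members of the miR-29 and miR-30 families were lower, or 3 adjusted over the list alone (fry adjusted p = 0.00250), as were 3 of 5 members of the miR-23/24/27 clusters, or 4 adjusted over the list alone (fry adjusted p = 0.00948). The miR-17/92 cluster and its paralogs had 3 of 5 members lower, or 3 adjusted over the list alone (fry adjusted p = 0.0107), and its mean of −0.54 turned to 0.13 under normexp. The growth and oncogenic list had 0 of 3 members past the threshold, also adjusted over the list alone, with a mean of −1.49 (fry adjusted p = 0.0453). The miR-15, miR-16, miR-103 and miR-107 families had 0 of 4 on either count (fry adjusted p = 0.128). In camera, which compares a list with the other miRNAs, only the G-rich list passed with an estimated correlation (adjusted p = 0.00422), while the lower lists did not (adjusted p from 0.512 to 0.704). Without scaling the miR-29 and miR-30 families and the miR-23/24/27 clusters passed (fry adjusted p = 0.0269 each), while the G-rich list, with a mean of 1.35, the growth list and the miR-17/92 cluster did not (fry adjusted p from 0.0585 to 0.0653). The A549 count rested on single arrays. It was 7 without the 24 h medium array of replicate 1, 8 without the 6 h medium array of replicate 1, 8 without the 24 h and 8 without the 2 h medium array of replicate 2, and 9 without the 2 h cell array of replicate 2. The raised baseline was present on 0 of 6 medium and 2 of 6 cell arrays, and 7 miRNAs, 4 higher and 3 lower, passed with it as a block, against 6, 3 higher and 3 lower, on the other arrays alone. The direction of the calls moved with scaling, to 3 higher and 10 lower without scaling, 5 and 26 in the deposited value table, and 5 and 4 without the guard on dim arrays.

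**Figure D1:**
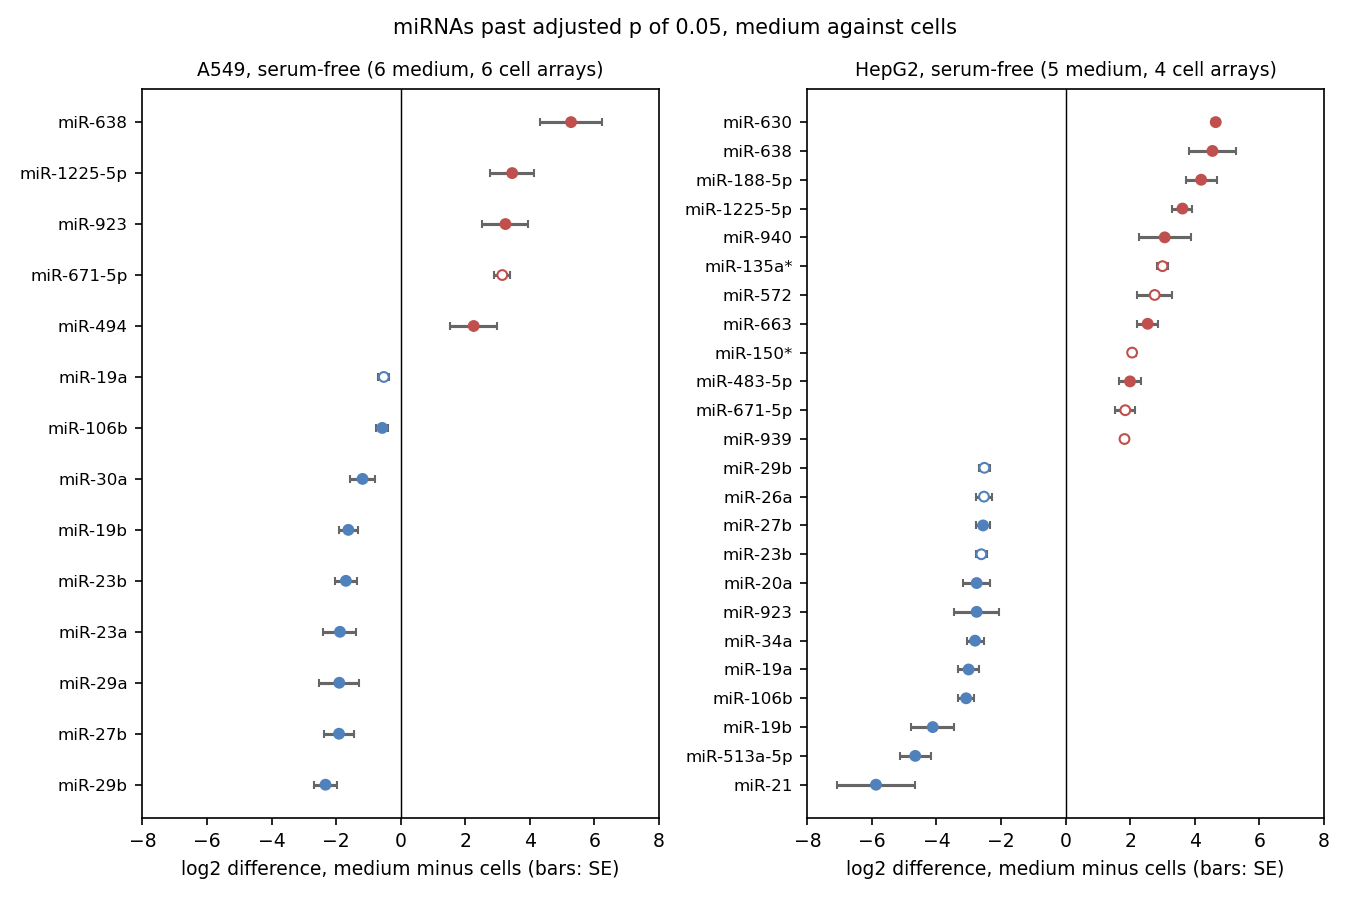
Log2 difference between medium and cells (horizontal axis) of the named miRNAs in serum-free A549 (6 medium and 6 cell arrays) and HepG2 (5 and 4), with points for the estimates, open where 1 arm was undetected or at the floor on all its arrays so that the size is not measured, and bars for 1 standard error. miR-638 lies at 5.28 in A549 and 4.55 in HepG2, while miR-923 lies at 3.25 in A549 and −2.76 in HepG2.

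In serum-free HepG2 more miRNAs passed the threshold than in A549, and some went the other way. miR-630 was 4.65 ± 0.10 higher in medium (5 medium and 4 cell arrays, adjusted p = 8.9e-06), miR-638 4.55 ± 0.73 higher, miR-188-5p 4.20 ± 0.48 higher and miR-1225-5p 3.62 ± 0.31 higher. miR-940 (3.07 ± 0.81), miR-663 (2.54 ± 0.32) and miR-483-5p (2.00 ± 0.35) followed. miR-135a*, miR-150* and miR-939 lay at the floor on all 4 cell arrays and were at least 6.65-fold, 3.45-fold and 2.90-fold higher. miR-572 and miR-671-5p, detected on 5 of 5 medium arrays and on 0 of 4 cell arrays, were at least 6.10-fold and at least 3.18-fold higher. miR-21 differed by −5.87 ± 1.20 (adjusted p = 0.0146) and was detected on 1 of 5 medium arrays. At 24 h its level was 3.00 on the medium array of replicate 2 and at the floor (−1.97) on that of replicate 1. miR-513a-5p (−4.66 ± 0.49), miR-19b (−4.11 ± 0.66), miR-106b (−3.08 ± 0.25), miR-19a (−3.00 ± 0.34), miR-34a (−2.80 ± 0.27), miR-923 (−2.76 ± 0.70), miR-20a (−2.75 ± 0.41) and miR-27b (−2.55 ± 0.22) were lower. Of these, miR-106b, miR-19a, miR-34a, miR-20a and miR-27b were detected on 1 of 5 medium arrays, and miR-513a-5p and miR-19b on 2. For these, and for miR-21, the size of the decrease is partly set by the floor. miR-23b, miR-29b and miR-26a, detected on no medium array, were at least 5.96-fold, 5.68-fold and 5.61-fold lower. miR-494, called higher in A549 medium, was at −1.14 ± 1.29 (adjusted p = 0.459). In total 60 of 112 tested miRNAs differed, 25 higher and 35 lower, 56 of them in the same direction at every time.

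By list in HepG2, 16 of 31 tested members of the G-rich list were higher and 3 lower, or 17 and 3 adjusted over the list alone (fry adjusted p = 3.0e-04). All 6 tested members of the miR-29 and miR-30 families were lower (fry adjusted p = 2.2e-05), as were 4 of 4 members of the miR-23/24/27 clusters (fry adjusted p = 6.5e-05) and 10 of 11 of the miR-17/92 cluster and paralogs (fry adjusted p = 0.00217). The counts adjusted over the list alone were the same for these 3 lists. The liver list had 3 of 5 members lower (fry adjusted p = 0.00217), among them miR-194, detected on no medium array and at least 4.14-fold lower, miR-148a at −1.58 ± 0.32 and miR-192 at −1.28 ± 0.39, but its mean of −0.89 became 0.17 without scaling. The p53 and hypoxia list had 2 of 3 lower (fry adjusted p = 0.00409), with a mean of −1.29 that became 0.069 without scaling, and the chromosome 14 cluster had 0 of 4 (fry adjusted p = 0.0573). Without scaling none of the 6 HepG2 lists that had passed did so. The mean went to 2.45 for the G-rich list (fry adjusted p = 0.187), −0.75 for the miR-29 and miR-30 families (fry adjusted p = 0.370), −0.95 for the miR-23/24/27 clusters and −1.23 for the miR-17/92 cluster (fry adjusted p = 0.192 each). No HepG2 list passed in camera with an estimated correlation (lowest adjusted p = 0.0755, adjusted p = 0.271 for the liver list and adjusted p = 0.376 for the p53 list). Many of the miRNAs undetected in 1 arm lie at the common floor there, so the size of their difference is partly set by the floor. The HepG2 count was 38, 36 and 36 without the 24 h (replicate 1), 30 h and 6 h medium arrays, and 38 and 34 without the 30 h and 6 h cell arrays. With the raised baseline (0 of 5 medium and 1 of 4 cell arrays) as a block, 33 passed, 10 higher and 23 lower, and 38, 10 higher and 28 lower, on the other arrays alone. Without scaling 27 passed, 24 higher and 3 lower, as the median over all tested miRNAs moved from 0.17 to 1.38. Quantile normalization gave 39 higher and 35 lower, and the deposited values 42 and 37.

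With serum present, medium and cells of A549 were compared again. miR-1225-5p was 6.48 ± 0.64 higher in medium (3 medium and 4 cell arrays, adjusted p = 0.00321), miR-638 4.93 ± 1.25 and miR-939 3.76 ± 0.73 higher. miR-575, at the floor on all 4 cell arrays, was at least 21.3-fold higher. Detected on 3 of 3 medium and 0 of 4 cell arrays, miR-663 was at least 29.4-fold higher, miR-630 at least 25.2-fold, miR-940 at least 21.9-fold, miR-483-5p at least 16.2-fold, miR-671-5p at least 14.5-fold, miR-150* at least 14-fold, miR-572 at least 11.8-fold and miR-134 at least 11.2-fold. miR-21 was lower by −5.59 ± 0.72 (adjusted p = 0.00673), with miR-29a at −3.15 ± 0.40, miR-24 at −2.84 ± 0.47, miR-22 at −2.16 ± 0.51, let-7i at −1.94 ± 0.42, miR-30a at −1.91 ± 0.31 and miR-19b at −1.85 ± 0.45. miR-21 was detected on 2 of 3 medium arrays and the others just named on 1 of 3. The size of these decreases is therefore partly set by the floor. miR-29b, miR-27a, miR-27b and miR-886-3p, detected on no medium array, were at least 4.41-fold, 4.35-fold, 3.52-fold and 2.14-fold lower, and let-7a, at the floor on all 3, at least 2.85-fold. In all, 44 of 94 miRNAs differed, 31 higher and 13 lower. Of the miRNAs called higher without serum, miR-923 was at 0.85 ± 0.47 (adjusted p = 0.193) and miR-494 at −1.88 ± 0.81 (adjusted p = 0.128).

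Of the G-rich list, 23 of 27 tested members were higher in A549 medium with serum and 0 lower, or 24 adjusted over the list alone (fry adjusted p = 5.2e-04). The chromosome 14 cluster had 2 of 3 higher (fry adjusted p = 6.4e-04), among them miR-134, which is also on the G-rich list. The miR-23/24/27 clusters had 3 of 5 lower, or 4 adjusted over the list alone (fry adjusted p = 0.00556), and the miR-29 and miR-30 families 3 of 5 (fry adjusted p = 0.0118). The growth list had 2 of 3 lower, miR-21 and miR-22 (fry adjusted p = 0.0250), and the let-7 family 2 of 4, or 3 adjusted over the list alone (fry adjusted p = 0.0554). The miR-17/92 cluster had 1 of 8 lower, or 0 adjusted over the list alone (fry adjusted p = 0.206), the miR-15, miR-16, miR-103 and miR-107 families 0 of 5 (fry adjusted p = 0.103) and the liver list 0 of 3 (fry adjusted p = 0.71). The counts adjusted over the list alone were the same for the lists where none is given here. Without scaling none of the 5 lists that had passed did so (fry adjusted p = 0.0716 each). None passed in camera with an estimated correlation (adjusted p = 0.128 for the G-rich list and from 0.486 to 0.688 for the others). The count was 27 without the 2 h medium array, 21 without the 24 h cell array and 26 without the 6 h cell array, and no array here had a raised baseline. Quantile normalization gave 28 higher and 20 lower, and the deposited values 26 and 32.

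HepG2 with serum gave a smaller tested set. Of the 35 miRNAs lower in serum-free HepG2 medium, 4 were tested here. miR-29b, miR-27b, miR-23b and miR-19b were detected on 3 of 4 cell arrays with serum, short of the 4 arrays needed for testing. The dimmest cell array detected 15 human miRNAs. Whether these families were lower in medium with serum is therefore not known. miR-134 was 3.37 ± 0.52 higher in medium (4 arrays each, adjusted p = 0.00155), miR-630 2.96 ± 0.36, miR-940 2.41 ± 0.36, miR-1225-5p 2.16 ± 0.56, miR-638 2.14 ± 0.53, miR-150* 2.07 ± 0.39, miR-483-5p 1.60 ± 0.39 and miR-572 1.57 ± 0.44 higher. miR-671-5p was at least 3.53-fold and miR-877 at least 1.27-fold higher, and the value of miR-877 became −0.0076 under normexp. miR-494 was lower by −7.82 ± 0.55 (adjusted p = 8.4e-05), miR-923 by −6.28 ± 0.86, miR-574-5p by −2.84 ± 0.42, miR-22 by −2.75 ± 0.40 and miR-92a by −2.22 ± 0.57, which became 0.53 without scaling. On the 4 medium arrays miR-22 was detected on 1, and miR-494, miR-574-5p and miR-92a on 2. miR-21, miR-574-3p, miR-197 and miR-21*, detected on no medium array, were at least 58.9-fold, 7.87-fold, 5.27-fold and 3.21-fold lower. Of 33 tested miRNAs 19 differed, 10 higher and 9 lower. The G-rich list had 8 of 21 higher and 2 lower, also adjusted over the list alone (fry adjusted p = 0.0364, camera adjusted p = 0.119 with an estimated correlation). The 33 tested miRNAs also set the scale, so this list, with 21 of them, was scaled largely against itself. The mean of this list was 0.35, or 2.40 without scaling (fry adjusted p = 0.0215), and with 1 array left out it ran from −0.67, without the dim 6 h cell array, to 0.025. Without the same array 60 miRNAs passed, against 35 without the 6 h medium array and 12 without the 24 h cell array. Of the 8 arrays 7 had a raised baseline (3 of 4 medium and 4 of 4 cell arrays). With it as a block 14 passed, 6 higher and 8 lower, and among the raised arrays alone 28, 7 higher and 21 lower. The direction of the calls moved with scaling, to 20 higher and 3 lower without scaling, 14 and 4 under quantile normalization, and 18 and 7 in the deposited value table, where the median over all tested miRNAs rose from 0.57 to 2.15, 1.40 and 1.49.

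**Figure D2:**
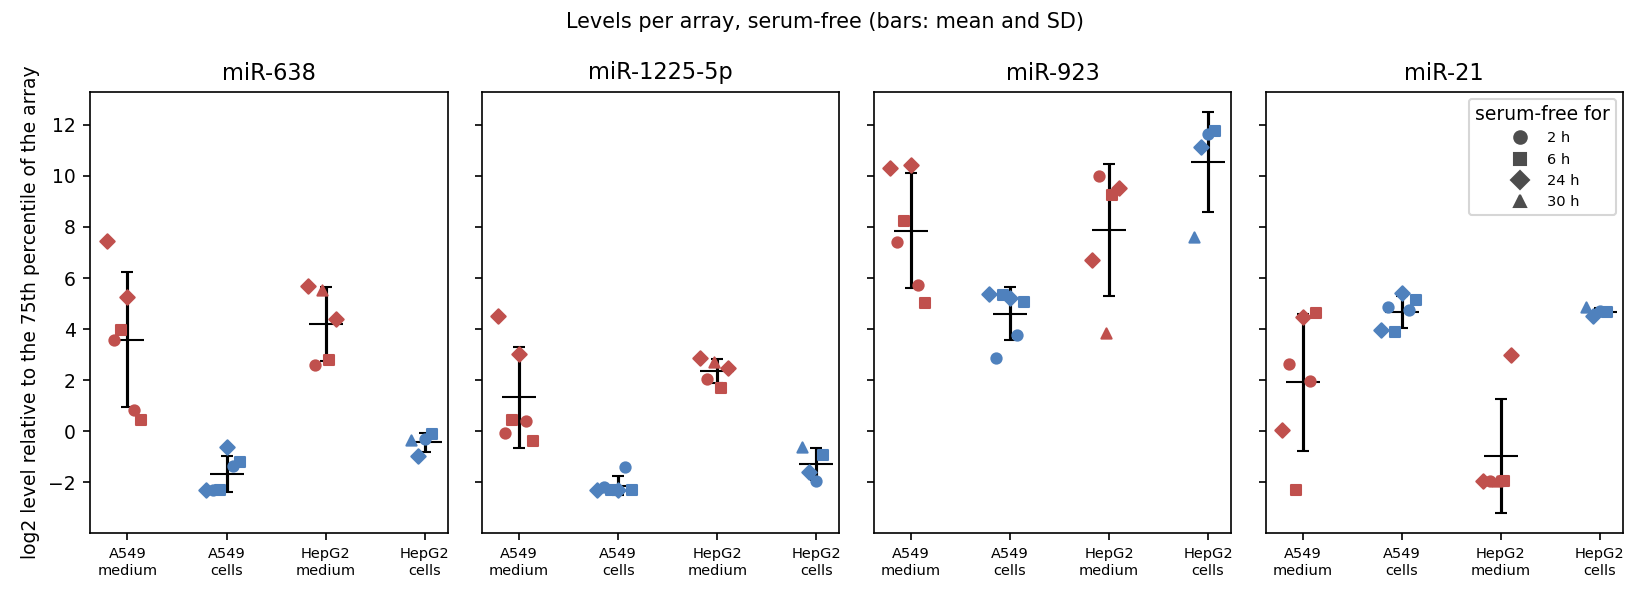
Log2 level of miR-638, miR-1225-5p, miR-923 and miR-21 on each serum-free array of A549 and HepG2, by compartment, with 1 point per array, a line for the mean and a bar for 1 standard deviation. The HepG2 cell arrays of miR-21 sit between 4.52 and 4.86, while the HepG2 medium arrays of miR-638 sit between 2.60 and 5.68, all above the HepG2 cell arrays of miR-638.

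The medium-associated miRNAs were partly shared between independent arrays. HepG2 serum-free and A549 with serum, which have no array in common, shared 17 miRNAs higher in medium among 72 tested in both, against 7.94 for independent lists, including miR-1225-5p, miR-638, miR-630 and miR-663. They shared 7 miRNAs lower in medium, against 2.53, among them miR-21, miR-24 and miR-29b. The serum-free comparisons of A549 and HepG2 shared 3 higher miRNAs, miR-1225-5p, miR-638 and miR-671-5p, against 1.13 for independent lists, and 8 lower ones against 5.16, among 31 tested in both. A549 with and without serum shared 3 higher miRNAs, the 3 just named, against 0.698, and 5 lower ones against 2.51, among 43 tested in both. With serum, A549 and HepG2 shared 10 higher miRNAs against 6.77 and 2 lower ones, miR-21 and miR-22, against 0.581.

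The number of human miRNAs detected varied widely between arrays, and by the rule of 50% of spots no difference between medium and cells passed the threshold with all arrays in. A549 serum-free medium arrays detected 39.3 ± 25.6 (SD, n = 6) and cell arrays 58.3 ± 27.2 (SD, n = 6), with a two-sided exact permutation p of 0.249. HepG2 medium arrays detected 92.6 ± 5.73 (SD, n = 5) and cell arrays 73.3 ± 42.2 (SD, n = 4), with an exact permutation p of 0.397. With serum the numbers were 71.7 ± 26.3 (SD, n = 3) and 65.0 ± 15.2 (SD, n = 4) in A549, with an exact permutation p of 0.686, and 35.0 ± 12.5 and 91.5 ± 52.3 (SD, n = 4 each) in HepG2, with an exact permutation p of 0.143. The HepG2 difference of 19.4 became 39.9 without the 30 h cell array, with an exact permutation p of 0.0357, and 8.27 without the 2 h cell array. It was 55.8 when 1 bright spot sufficed, with an exact permutation p of 0.0317, and 51.95 with detection from negative-control spots, with an exact permutation p of 0.0952. The A549 difference of −19.0 became −8.87 without the 2 h cell array of replicate 2, −12.7 without the 6 h medium array of replicate 1, −7.67 with detection from negative-control spots and 3.5 when 1 bright spot sufficed for detection.

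The medium-minus-cells difference itself differed between HepG2 and A549. For miR-923 the interaction was −4.74 ± 0.92 (adjusted p = 0.00273), since it was higher in A549 medium and lower in HepG2 medium. miR-513a-5p differed by −5.25 ± 0.93, miR-106b by −1.90 ± 0.33, miR-19a by −1.84 ± 0.32, miR-34a by −1.73 ± 0.40, miR-30e by −1.50 ± 0.19 and miR-194 by −1.47 ± 0.29. miR-197 was 2.54 ± 0.91 more medium-associated in HepG2, miR-135a* 2.43 ± 0.70, miR-328 2.40 ± 0.61, miR-885-5p 2.35 ± 0.59, miR-663 2.14 ± 0.70, let-7d* 2.05 ± 0.55, miR-150* 2.01 ± 0.43, miR-765 1.89 ± 0.31, let-7b* 1.61 ± 0.43 and miR-211 1.56 ± 0.53. In the serum-free HepG2 fit miR-135a*, miR-150*, miR-765, let-7d* and miR-211 lay at the floor on all 4 cell arrays. The size of their interactions may therefore be partly set by the floor. Over 21 arrays, 43 of 141 miRNAs had an interaction past the threshold, 29 more and 14 less medium-associated in HepG2. For 9 of the 43, all arrays of 1 line lay at the floor, so no difference was measured in that line and the interaction only repeats the other line's difference. These include miR-26a, miR-424*, miR-455-3p, miR-106a/miR-17 and miR-148a, at the floor in A549 and lower in HepG2 medium than in HepG2 cells, and miR-30a, at the floor in HepG2 and lower in A549 medium. A further 4, among them miR-629*, were detected on no A549 array. Without scaling limma called 0, with 25 at an unadjusted p under 0.05, miR-34a turned to 0.18 and miR-194 to 0.051, and under normexp let-7b* turned to −0.037 and miR-211 to −0.044.

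By list, 4 of 11 members of the miR-17/92 cluster and paralogs were less medium-associated in HepG2, also adjusted over the list alone, with a mean of −1.10 (fry adjusted p = 5.9e-04, camera adjusted p = 0.0812 with an estimated correlation) that was −0.18 without scaling. The G-rich list went both ways, with 7 of 33 more and 3 less medium-associated, or 5 and 3 adjusted over the list alone (fry adjusted p = 0.262, mixed adjusted p = 9.7e-12). The other 8 lists tested had fry adjusted p from 0.244 to 0.760. Of these, the liver list had 1 more and 2 less (mixed adjusted p = 0.0107), the miR-29 and miR-30 families 1 and 2 (mixed adjusted p = 0.00338), the p53 list 1 and 1, and the let-7, growth, miR-15/16, miR-23/24/27 and chromosome 14 lists 0. The interaction count was 22, 27 and 23 without the A549 medium arrays at 2 h (replicate 1), 6 h (replicate 1) and 24 h (replicate 2). It was 23, 22, 23 and 24 without the A549 cell arrays at 24 h and 6 h of replicate 1 and at 24 h and 6 h of replicate 2, and 23, 18 and 17 without the HepG2 medium arrays at 24 h (replicate 1) and 6 h and the HepG2 cell array at 6 h. With the raised baseline (3 of 21 arrays) as a block 38 passed, 24 higher and 14 lower, and on the other arrays alone 29, 12 higher and 17 lower. The split was 12 and 17 with scaling over all human miRNAs, 6 and 16 under quantile normalization, 15 and 12 in the deposited value table and 14 and 14 without the guard.

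Serum-free and serum arrays were then compared within each compartment. In medium, an effect of serum deprivation on the cells cannot be told apart from RNA carried in with the serum. In A549 medium 4 of 73 miRNAs differed, all lower without serum (7 serum-free and 4 serum arrays). miR-1225-5p was lower by −2.34 ± 0.25 (adjusted p = 0.00292), miR-150* by −1.89 ± 0.29 and miR-765 by −1.0 ± 0.12. miR-451, an erythroid miRNA, was detected on 4 of 4 serum arrays and 0 of 7 serum-free arrays and was at least 2.85-fold lower without serum (adjusted p = 0.00939). Of the G-rich list, 3 of 29 were lower, also adjusted over the list alone (fry adjusted p = 2.3e-04, camera adjusted p = 0.00467 with an estimated correlation), and without scaling its mean went from −0.73 to −1.47 and did not pass (fry adjusted p = 0.313). The let-7, miR-17/92, miR-23/24/27 and chromosome 14 lists had 0 members past the threshold over all miRNAs and fry adjusted p from 0.221 to 0.814. Adjusted over the list alone, 1 member of the miR-23/24/27 clusters was higher. Without the serum-free 24 h array of replicate 1 the count was 7, without scaling it was 1, and with scaling over all human miRNAs it was 13. The direction split was 1 higher and 9 lower under quantile normalization, 1 and 2 in the deposited value table and 2 and 4 without the guard.

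**Figure D3:**
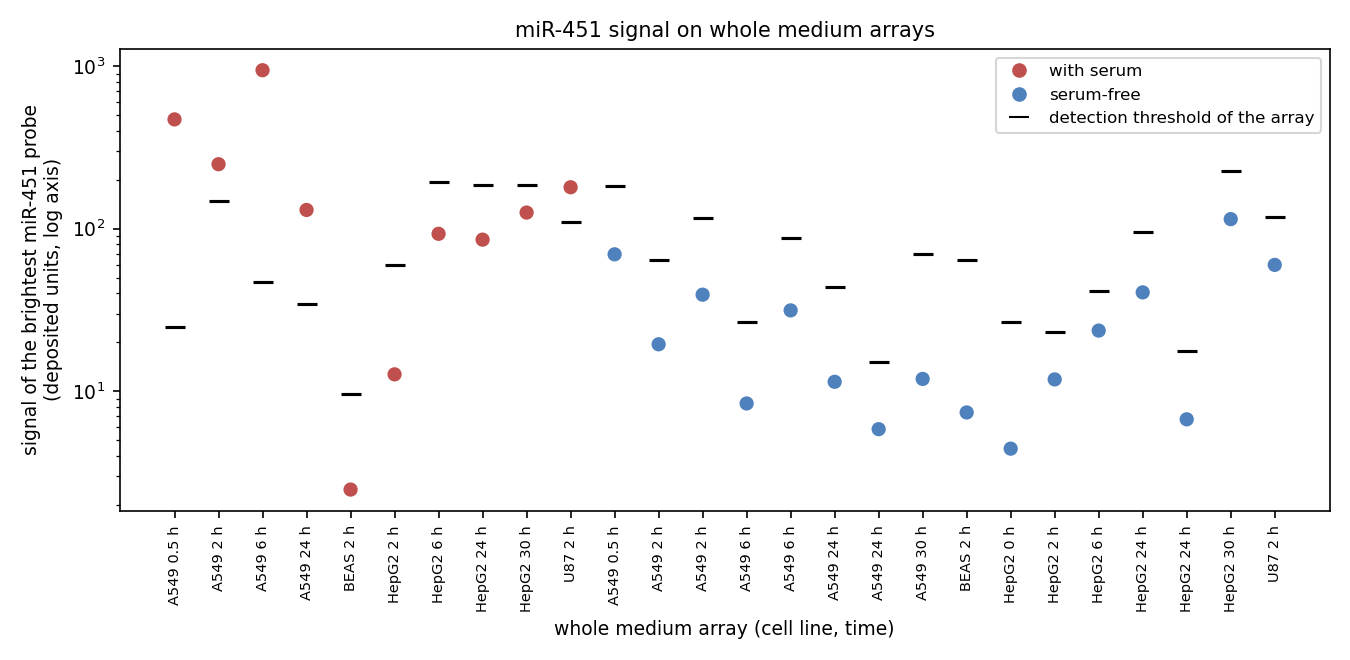
Intensity of miR-451 (points, logarithmic axis) and the detection threshold (dashes) on each whole medium array, by cell line and serum. The 4 A549 serum arrays lie between 130.2 and 943.4, each above its threshold, and the 8 A549 serum-free arrays lie below theirs.

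HepG2 medium had 2 of 78 miRNAs past the threshold between serum-free and serum arrays, and 23 at an unadjusted p under 0.05. miR-135a* was 1.77 ± 0.14 higher without serum (5 and 4 arrays, adjusted p = 0.00330) and miR-877 was lower by −1.60 ± 0.19 (adjusted p = 0.0142). Neither of its tested lists passed the directional test, with 0 of 29 members of the G-rich list past the threshold (fry adjusted p = 0.667, mixed adjusted p = 0.00425) and 0 of 4 of the chromosome 14 cluster, or 1 higher adjusted over the list alone (fry adjusted p = 0.137). The mean of the G-rich list was 0.25 and its median −0.051, and camera placed it below the other miRNAs (adjusted p = 0.00164 with the preset correlation and 0.133 with an estimated correlation). The count was 1 without the serum-free arrays at 24 h (replicate 1) or 30 h or the serum arrays at 24 h or 2 h, 13 without the serum-free 24 h array of replicate 2 and 0 without the serum array at 6 h. The raised baseline was on 0 of 5 serum-free and 3 of 4 serum arrays. As a block it left 0 miRNAs, and without those arrays, where 1 serum array at 2 h remains, assumed to vary like the rest, 43 were higher and 0 lower, so serum and baseline cannot be told apart here. Scaling moved the split to 4 higher and 2 lower under quantile normalization, 8 and 3 in the deposited value table, and 1 and 0 without scaling or with scaling over all human miRNAs. The difference between lines was tested directly, and limma called 0 of 123 miRNAs, with 12 at an unadjusted p under 0.05. The G-rich list had a mean interaction of 0.72 with 0 of 37 past the threshold (fry adjusted p = 0.0905), and the other 6 lists had 0 members past it (fry adjusted p from 0.471 to 0.645). With the raised arrays left out, 39 passed, 38 of them higher in HepG2, on the same lone serum array, and with them as a block 1 passed. The count was 1 without any of 5 arrays, the A549 serum-free arrays at 2 h of replicates 1 and 2, the A549 serum arrays at 24 h and 2 h, and the HepG2 serum-free array at 24 h of replicate 2.

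In cells, serum deprivation moved no miRNA past the threshold. In A549 cells limma called 0 of 71 (6 and 4 arrays), with 2 at an unadjusted p under 0.05, the larger of them miR-494 at −3.27 ± 0.59 (adjusted p = 0.0522), named after its values were seen. The count was 1 without the serum-free cell arrays at 24 h of replicate 1, or at 24 h, 2 h or 6 h of replicate 2, or the serum array at 2 h of replicate 2. In HepG2 cells limma called 0 of 82 (4 arrays each), with 17 at an unadjusted p under 0.05, among them miR-26a at 1.73 ± 0.36, miR-638 at −1.89 ± 0.40 and miR-1225-5p at −1.59 ± 0.31 (adjusted p = 0.103 each), also named after their values were seen. Each tested list had 0 members past the threshold over all miRNAs in both lines (fry adjusted p from 0.724 to 0.811 over 8 lists in A549 and from 0.330 to 0.487 over 8 lists in HepG2). Adjusted over the list alone, the G-rich list had 1 lower member in A549 and 2 in HepG2, and the liver, miR-23/24/27 and miR-29 and miR-30 lists had 1 higher member each in HepG2. A raised baseline was on 2 of 6 against 0 of 4 A549 arrays and 1 of 4 against 4 of 4 HepG2 arrays, and the HepG2 count with it as a block was 0. Across 4 lines at 2 h, 2 of 31 miRNAs were lower in serum-free medium (5 and 4 arrays), miR-575 by −2.22 ± 0.45 and miR-1225-5p by −2.04 ± 0.45 (adjusted p = 0.0440 each). Of the G-rich list 2 of 21 were lower there, or 3 adjusted over the list alone (fry adjusted p = 0.0537, mixed adjusted p = 0.0153). This count was 0 without the A549 serum-free array of replicate 1, the U87 serum-free array or the A549, HepG2 or U87 serum array, 1 without the BEAS serum array, 6 without the A549 serum-free array of replicate 2, and 0 on the arrays without a raised baseline (1 of 5 and 1 of 4 had it).

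To follow release with time, slopes on the logarithm of hours were fitted in serum-free medium. In A549, 4 of 34 miRNAs rose over 8 arrays from 0.5 to 30 h, miR-630 by 1.61 ± 0.45 for each doubling of hours plus 1, miR-494 by 1.01 ± 0.25, miR-572 by 0.88 ± 0.23 and miR-575 by 0.76 ± 0.18 (adjusted p from 0.0346 to 0.0418). All 4 are on the G-rich list, of which 4 of 18 rose, or 5 adjusted over the list alone (fry adjusted p = 0.0176, camera adjusted p = 0.0334 with an estimated correlation), while the miR-23/24/27 clusters had 0 of 4 (fry adjusted p = 0.253). The mean slope of the G-rich list was 0.35, 0.20 without scaling, where the list did not pass (fry adjusted p = 0.390), and as low as 0.049 with 1 array left out. The A549 slopes had no term for the replicate number. miR-630 lay at 2.23, 2.78 and 5.61 at 2, 6 and 24 h in replicate 1. In replicate 2 it lay at the floor at 2 and 6 h and at 2.37 at 24 h. The 0.5 h and 30 h times had 1 array each, so these slopes may mix an offset between replicates with time. In HepG2, miR-638 rose by 0.57 ± 0.079 and miR-572 by 0.57 ± 0.062 over 6 arrays from 0 to 30 h, while miR-513a-5p changed by −1.01 ± 0.19, miR-574-3p by −0.83 ± 0.14 and miR-324-3p by −0.60 ± 0.093 (adjusted p from 0.0184 to 0.0464). These were the 5 of 92 tested that passed. The G-rich list had 2 of 32 rising and 1 falling, or 4 and 4 adjusted over the list alone (fry adjusted p = 0.643, mixed adjusted p = 6.0e-04), and the chromosome 14 cluster 0 of 5 (fry adjusted p = 0.643). Without scaling the A549 calls were 4 rising and 4 falling, limma called 0 in HepG2, and the deposited value table gave 5 rising and 1 falling in HepG2. The A549 count was 0 without any of the arrays at 0.5 h, 24 h (replicate 1) or 2 h, 6 h and 24 h of replicate 2, 1 without 30 h and 10 without 2 h of replicate 1. The HepG2 count was 0 without the arrays at 2 h, 6 h, 24 h (replicate 1) or 30 h and 3 without 0 h.

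Fractions of medium asked where extracellular miRNAs travel, with pellets holding material that sediments. Between pellets and concentrated supernatants of A549, HepG2, U87 and T98 medium (5 pairs), limma called 0 of 60 miRNAs, with 7 at an unadjusted p under 0.05. miR-671-5p was 2.54 ± 0.73 higher in pellets (adjusted p = 0.242), chosen after its values were seen, and the G-rich list had 0 of 32 past the threshold (fry adjusted p = 0.108, mixed adjusted p = 0.0261). The labels leave 3 of the pairs in doubt, since both U87 supernatants are also labelled concentrated pellet, and the T98 pellet has no serum status stated while its supernatant was with serum. Without the U87 pairs 1 miRNA passed. Scaling over all human miRNAs made 31 lower in pellets and 0 higher, and no scaling made 18 lower and 0 higher, as the median over all tested miRNAs moved from −0.14 to −1.99 and −1.34. Of the 5 pellet arrays 4 were so dim that the guard set their divisor, against 0 of 5 supernatant arrays, so brightness follows this contrast almost fully. The count was 1 without the HepG2 pellet array. A raised baseline was on 2 of 5 pellet and 2 of 5 supernatant arrays, and 1 miRNA passed on the other arrays alone.

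The remaining comparisons have 1 array per condition and no test. Among the values below, those of miR-940 and miR-765 after RNase, miR-100, miR-638 and miR-886-3p in T98, miR-638 and miR-1225-5p in BEAS and in U87 with serum, and miR-21 in the A549 concentrated supernatant have 1 of their 2 arrays at the floor, so their size is set in part by the floor. RNase in the HepG2 serum-free medium at 30 h left 26 human miRNAs detected, against 88 without it, and 20 on both arrays. The scaling divisor fell to 0.147 of that of the untreated medium. Without scaling, miR-940 was lower by −7.30 after RNase, miR-638 by −4.79, miR-630 by −4.58 and miR-671-5p by −3.30, while miR-923 changed by −0.50, miR-557 by 0.69, miR-1225-5p by 0.82 and miR-765 by 1.71. In T98, the nuclear array detected 34 miRNAs and the cytoplasmic array 19. let-7b was 3.55 higher in the nucleus and miR-100 1.67 higher, while miR-638 was lower by −3.18, miR-886-3p by −2.26 and miR-923 by −2.11. Of the let-7 family 7 members were detected in the nucleus and 1 in the cytoplasm, so its median of 2.08, above 99.8% of random lists matched on level, is taken against the floor, and it was 1.66 with undetected members at the detection threshold.

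With serum at 2 h, U87 medium detected 32 miRNAs and U87 cells 89. miR-638 was 7.14 higher in medium, miR-1225-5p 4.51 higher and miR-923 3.80 higher, while miR-21 was lower by −6.47 and miR-125b by −3.98. The G-rich list had a median of 1.71 over 25 members, above all random lists, with 23 detected in medium and 9 in cells, and 1.5 without scaling. The mesenchymal list had −1.96 over 4 members, above 4.57% of random lists, and −1.49 with undetected members at the threshold. BEAS medium detected 31 miRNAs and BEAS cells 75. The G-rich list had a median of 2.34 over 12 members, above 98.4% of random lists, but −0.014 without scaling and 0.58 with scaling over all human miRNAs, where the median over all detected miRNAs moved from 0 to −2.17 and −1.42. Under these 2 settings the list lay above 99.86% and 99.99% of random lists. In BEAS the epithelial list had −0.55 over 5 members, above 3.86%, but 0 with undetected members at the threshold. Lower still among random lists were the miR-23/24/27 clusters, at −1.57 over 5 members, above 0.88%, and −0.79 with undetected members at the threshold. The miR-17/92 cluster and paralogs had −0.34 over 10 members, above 1.3%, and 0 with undetected members at the threshold. The BEAS medium array was dim. With the scaling undone after the floor had been applied, miR-1225-5p went from 5.42 to 0.12, miR-638 from 3.36 to −1.94 and miR-21 from −2.37 to −7.67. For miR-1225-5p and miR-638 the BEAS cell array lay at the floor, so 0.12 and −1.94 are lower bounds. The direction of miR-638 without scaling is therefore not measured, whereas miR-21 was lower both ways. In serum-free U87 the medium detected 16 miRNAs and the cells 9, and miR-638 was 2.75 higher in medium while miR-1225-5p was lower by −1.10. The G-rich list had a median of 0 there over 11 members, above 12.7% of random lists, and of 2.56 in the deposited value table, above 95.3%.

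Among A549 medium fractions, 51 miRNAs were detected before the spin, 13 in the pellet, 63 in concentrated medium and 112 in the concentrated supernatant. miR-671-5p was 3.87 higher in the pellet than before the spin and miR-1225-5p 2.32 higher, while miR-494 was lower by −2.59 and miR-923 by −1.65. In the concentrated supernatant miR-638 was 2.83 higher and miR-21 lower by −6.84. The G-rich list had a median of 0.40 over 14 members in the A549 pellet. It was 1.25 over 37 members in concentrated medium and 0.63 over 38 in the concentrated supernatant. Each lay above 99.985% or more of random lists. With undetected members at the threshold these medians were 0.34, 1.10 and 0.087. In HepG2 the detected numbers were 70 before the spin, 29 in the pellet, 142 in concentrated medium and 153 in the concentrated supernatant, and miR-630 was 2.73 higher and miR-494 lower by −4.79 in the pellet. T98 concentrated supernatant detected 319 miRNAs against 253 in the original control medium. Its neural list had a median of −0.39 over 5 members, above 3.78% of random lists, and its chromosome 19 list 0.61 over 6 members, above 76.5%. Its let-7 list had −0.51 over 9 members, above 2.82%, its miR-23/24/27 list 0.39 over 5, above 96.5%, and its G-rich list 0.17 over 46, above 99.2%, but −0.090 with scaling over all human miRNAs. The T98 pellet detected 80 against 59 in the original medium, with miR-494 lower by −6.04, miR-923 by −3.62, let-7b by −3.54 and miR-638 by −2.07. The U87 arrays labelled concentrated pellet detected 64 miRNAs with serum and 77 without, against 10 and 8 on those labelled original pellet. Whether these hold pellets or medium is not clear from the labels.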

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

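Among the tests below, the 3 on the medium-associated pattern, the one on scaling for the difference between lines and the one on release of miR-451 were chosen only after the result was seen, as were the bound of 2 standard errors and the look at detection thresholds for miR-451.

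The first pattern is that minor miRNAs such as miR-638 and miR-1225-5p were higher and family miRNAs such as miR-29b were lower in medium than in cells. Scaling stays open as a cause for both directions in HepG2. Without it the higher calls had a median difference of 2.80 (median standard error 0.34 with and 0.91 without scaling). The median over all tested miRNAs was 1.38 without scaling, so those called higher after scaling were bound to lie mostly above 0. The lower calls were raised by the same shift. Their median of −1.10, with 88.6% below 0, lies within 2 standard errors (0.27 with and 0.89 without). Signal already in the medium at 0 h stays open too, as the 0 h array differed from the mean of the later arrays by −0.81 in the median and 20 of 25 miRNAs were lower on it. Hybridization without a matching miRNA may contribute in serum-free HepG2, where medium arrays detected 10.2 viral features, which these cells should not hold, and cell arrays 2.25 (exact permutation p of 0.0159, n = 5 and 4). The numbers were 10.3 and 3.5 in A549 with serum, with all medium arrays above all cell arrays (exact permutation p of 0.0571, the smallest that 3 and 4 arrays can give), 3.83 and 2.67 in serum-free A549 (exact permutation p of 0.496) and 5.75 and 4.75 in HepG2 with serum (exact permutation p of 0.743), so it stays open there, as does selective export in both lines.

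The second pattern is the difference between lines, noted because 43 miRNAs had an interaction past the threshold, because miR-923 went opposite ways (interaction −4.74) and because the miR-17/92 cluster and paralogs had a mean interaction of −1.10. Dim A549 medium arrays fit as part of the cause, since without the 2 h and 6 h arrays of replicate 1 the count was 18. That test is not specific, as the count was 17 without the 6 h HepG2 cell array alone. Whether scaling produced it cannot be told apart from lost precision, since the count was 0 without scaling while the median absolute difference went from 1.52 to 1.47 and the standard error from 0.39 to 0.76. Those lower in HepG2 shrank from −1.71 to −0.48 and those higher went from 1.47 to 1.77, and a difference in what the lines export stays open as the biological explanation.

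The third pattern is miR-451 in A549 medium with serum, detected on 4 of 4 such arrays, on 0 of 8 serum-free A549 medium arrays and on 0 of 10 A549 cell arrays. Carry-in with the serum stays open, although 1 of 6 serum medium arrays of HepG2, BEAS and U87 detected it, fewer than a source common to all lines was to give, and 0 of their 8 serum-free arrays did. That bound was set wrongly, since on 3 of the 6, all HepG2, the threshold of 184.7 to 193.3 lies above the lowest A549 signal of 130.2. On the HepG2 array at 2 h (signal 12.7, threshold 59.7) and the BEAS array (2.48 and 9.63) such a signal would have passed. These signals are not scaled between arrays, and the BEAS array was dim. An equal share of miR-451 could have given less signal there, so these 2 arrays do not count against carry-in. The A549 serum control (160.4 over a threshold of 54.6) and the A549 control with no serum status stated (100.8 over 71.3) also detected it, which goes with carry-in, while the HepG2 serum control did not (171.7 under 256.7). miR-122 was detected on 2 of 4 A549 serum medium arrays and 0 of 8 serum-free ones, but also on 2 of 6 serum-free HepG2 medium arrays. Of the blood cell and serum list, miR-144, miR-486-5p and miR-223 were detected on none of the A549 serum medium arrays. Release by the cells stays open as well, since 0 cell arrays with miR-451 detected does not exclude export of all that was made. The signal did not build up with time, at 470.0, 249.0, 943.4 and 130.2 on the A549 serum arrays at 0.5, 2, 6 and 24 h. With 1 array per time this does not decide the question.

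Of 100 series of values tested for 1 array far from the others, 9 had such an array, and chance gives about 1 in 20. The background stood apart on the A549 serum-free cell array at 2 h of replicate 1 (320.6), the HepG2 serum-free cell array at 30 h (44.7), the HepG2 serum medium array at 2 h (12.3) and the HepG2 serum cell array at 6 h (34.1). The 30 h HepG2 serum-free cell array also stood apart in miR-483-5p (−1.97), miR-923 (7.62) and miR-29b (1.17). The others were miR-939 on the HepG2 serum-free medium array at 24 h of replicate 2 (−0.44) and miR-630 on the HepG2 serum cell array at 24 h (−1.08). No explanation was tested for these.

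Of the viral miRNA features, which no comparison used as a result, 6 passed detection on 50% or more of the medium arrays. kshv-miR-K12-3 was detected on 52 of 52 medium and 18 of 26 cell arrays, ebv-miR-BART13 on 34 and 9, hcmv-miR-UL70-3p on 32 and 2, hsv1-miR-H1 on 31 and 1, hsv1-miR-LAT on 30 and 1 and hcmv-miR-US4 on 26 and 0. Others went the other way, with ebv-miR-BART12 on 13 and 15 and kshv-miR-K12-12 on 1 and 6.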

How the results depend on the processing

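Chosen only after the data were seen were the tests without the guard, without background subtraction, with means over spots, with negative-control spots, without dim arrays, with A549 second samples alone and by raised baseline, and the use of list medians minus those of random lists for single arrays. Of the values of named miRNAs under other settings, 1578 of 1982 kept their direction and side of the threshold, 396 lost the threshold and 8 reversed, and of those with 1 array left out 1027 of 1342 kept both and 315 lost the threshold. The HepG2 cells count of serum effects stayed at 0 under all settings but 1. Signal over background limits all counts, since most features lie at the floor on most arrays. The slide as a block and the scanner's own detection calls were not run, because the files used here give neither. Except where a setting tests more or fewer miRNAs or leaves out arrays, the cause of a change was not tested.

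Scaling over all human miRNAs gave 7 for A549 serum-free medium against cells, 27 for A549 with serum, 13 for serum-free against serum in A549 medium, 1 in HepG2 medium, 4 across 4 lines, 9 and 2 for the A549 and HepG2 slopes, 6 for the serum interaction, 31 for pellets and 2.28 for BEAS. No scaling gave 27 for HepG2 serum-free, 1 for A549 cells, 1 for A549 medium, 1 for HepG2 medium, 5 across lines, 8 and 0 for the slopes, 0 for the medium interaction, 2 for the serum interaction, 18 for pellets, 2.34 for U87 with serum and 1.49 for the A549 concentrated supernatant. It reversed miR-92a in HepG2 with serum (0.53) and the interactions of miR-34a (0.18) and miR-194 (0.051). Quantile normalization gave 10 for A549 medium, 6 for HepG2 medium, 0 across lines, 0 and 0 for the slopes, 22 for the medium interaction and 1 for the serum interaction. The deposited value table gave 31 for A549 serum-free, 11 for HepG2 medium, 2 for the A549 slope, 27 for the medium interaction, 1 for the serum interaction, −2.49 for the T98 nucleus, 2.20 for U87 serum-free, 3.11 for U87 with serum and 2.21 for BEAS.

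Normexp gave 1 for A549 cells, 1 for A549 medium, 1 for HepG2 medium, 5 across lines and 10 and 11 for the slopes, and reversed miR-106b (0.17) and miR-19a (0.28) in A549 serum-free, miR-877 (−0.0076) in HepG2 with serum, and the interactions of let-7b* (−0.037) and miR-211 (−0.044). With no filter, which tests more miRNAs, the counts were 1 for A549 serum-free, 19 for HepG2 serum-free, 13 for A549 with serum, 0 for HepG2 with serum, 2 for A549 medium, 0 for HepG2 medium, 0 across lines, 0 and 0 for the slopes and 15 for the medium interaction. Detection on all arrays of an arm gave 1 for A549 cells, 6 for HepG2 medium, 0 and 10 for the slopes, 23 for the medium interaction and 1 for the serum interaction. The brightest probe gave 1 for A549 cells, 6 for HepG2 medium, 0 across lines, 12 for the HepG2 slope, 1 for the serum interaction and 1 for pellets. A mean-variance trend gave 1 for A549 cells, 1 for HepG2 medium, 0 across lines and 9 for the A549 slope. No time factor gave 1 for A549 cells and 7 for A549 medium, and added control arrays gave 26 for A549 with serum and 1 for A549 cells. Without the U87 pairs 1 miRNA passed for pellets. Detection by 1 spot turned the difference in detected miRNAs to 3.5 in A549 and made it 55.8 in HepG2, past the threshold.

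No guard gave 9 for A549 serum-free, 1 for the A549 slope and 28 for the medium interaction. Omitting dim arrays gave 60 for HepG2 with serum, 21 for the A549 slope and 18 for the medium interaction, and A549 second samples alone gave 12 for the latter. No background subtraction gave 2 for A549 cells, 5 for HepG2 cells, 1 across lines and 17 for the medium interaction. Negative-control spots gave 1 for A549 cells, 7 for HepG2 medium, 1 for the HepG2 slope and 1 for the serum interaction. Means over spots gave 7 for A549 medium, 0 across lines and 2 for the A549 slope. The raised baseline as a block gave 7 for A549 serum-free, 33 for HepG2 serum-free, 0 for HepG2 medium and 1 for the serum interaction. The arrays without it gave 6, 38, 43 and 39 for these 4, 0 across lines and 1 for pellets. The replicate number as a block gave 17 for A549 serum-free, where a pairing of the samples is not established.

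With each array left out in turn, the counts ran from 7 to 18 for A549 serum-free, 34 to 68 for HepG2 serum-free, 21 to 65 for A549 with serum, 12 to 60 for HepG2 with serum, 0 to 1 for A549 cells, 3 to 7 for A549 medium, 0 to 0 for HepG2 cells, 0 to 13 for HepG2 medium, 0 to 6 across lines, 0 to 10 and 0 to 6 for the A549 and HepG2 slopes, 17 to 53 for the medium interaction, 0 to 1 for the serum interaction and 0 to 1 for pellets. The difference in detected miRNAs ran from −24.9 to −8.87 in A549 and from 8.27 to 39.9 in HepG2.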

Other observations

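Other splits of the same arrays, planned before the result was seen, were fitted for each comparison of groups, and those with arms exchanged only within a time or line were chosen after it. Chance is excluded as the source of a count where at most 5 in 100 splits gave as many miRNAs as the real one, which is included in each number. This held for A549 serum-free medium against cells (2 of 100, with 14 in the real split and 15 as the highest other, a split that moves 2 arrays and matches the real one on 10 of 12), also within times (2 of 100, again 15). It held for HepG2 serum-free (1 of 100, 60 against 31, and 1 of 24 within times, again 31). For the medium interaction, arms were exchanged within lines but not within times (1 of 100, 43 against 38). These exchanges also remove the difference between medium and cells that the lines share. They therefore cannot exclude chance for a difference between lines. Over all splits, which ignore the times, the rule held for A549 with serum (1 of 34, 44 against 3) and HepG2 with serum (1 of 32, 19 against 0). Within times these 2 have 12 and 8 splits, too few for a share under 0.05, with 0 as the highest other in each. For serum effects the rule held across 4 lines (2 of 100, 2 against 2, and 1 of 24 within lines, 2 against 0). That count is only 2 miRNAs, fell to 0 with single arrays left out, and 1 of 24 is the smallest share possible. Chance is therefore not taken as excluded across lines. In A549 medium it held over all splits (2 of 100, 4 against 5) but not within times (3 of 54, 4 against 10), so chance is not excluded there. In HepG2 medium 4 of 100 splits, and 3 of 24 within times, gave as many as the real 2, so chance is not excluded there either, and one of the former gave 34, which points to a structure of the samples. That split sets both serum-free 24 h arrays with the serum arrays at 24 h, 6 h and 2 h, and the raised baseline as a block left 0 miRNAs. Where the real split called 0 miRNAs every split gives as many, so the number says nothing about chance. This is so for A549 cells (100 of 100, highest other 6), HepG2 cells (32 of 32, highest other 0), pellets (100 of 100, highest other 6) and the serum interaction (100 of 100, highest other 26, in a split that divides the HepG2 arrays as above and points to the same structure).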
